A study of Mus musculus with 2 samples.

How the data were processed

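The series profiled microRNAs (miRNAs) by small-RNA sequencing in limb tissue of mixed-sex B6NCrl mouse embryos at embryonic day 10.5. Per the labels, the 2 libraries are biological replicates of 1 group, each made from a pool of embryos: 69 embryos for replicate 1 and 51 for replicate 2. Replicate numbers were taken from the labels. With 1 group there was no contrast between conditions, and every comparison below is between genes, between gene lists or between these 2 libraries.

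The deposited tables hold raw read counts per gene, not normalized, with 1 table per library. Per the deposited readme texts, the reads were aligned to the mouse assembly mm10 and counted over the GENCODE M4 annotation, 1 alignment per library and without pooling the replicates. The aligner, the counting program, adapter trimming and their versions are not given in the sources used here. From the values, each table has 3 count columns (both strands together, the sense strand and the antisense strand) and 4 rows for reads given to no gene: unmapped, multimapping, outside genes and ambiguous. Each column summed with those rows to the same library total, which is the layout of counting uniquely placed reads in 3 strand settings. A read that matches several loci equally well is then given to none of them. This can lower the count of a miRNA gene whose mature sequence is encoded at more than 1 locus. A table counts reads per miRNA gene (hairpin), so the 5' and 3' arms of a hairpin were not separated.

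The tables cover 1973 miRNA genes by Ensembl identifier. Symbols, coordinates (1-based), host genes and hairpin sequences were taken from the GENCODE M21 annotation of GRCm38, the same build as mm10. Of the identifiers, 1894 matched by ID and 79 did not and were kept under their identifiers. A host gene is an annotated gene on the same strand that spans the whole hairpin, and a hairpin was called exonic if it overlapped any annotated exon of that host.

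The sense counts were the main measurement. Reads totalled 10064833 in replicate 1 and 7218612 in replicate 2, of which 32.3% and 18.6% were unmapped, 21.9% and 25.4% mapped to several loci and 10.3% and 6.46% lay outside the annotated genes. No read was ambiguous. The sense counts assigned to genes came to 3581672 and 3576482, and CPM, the counts per 1000000 sense counts in genes, were computed from those totals. A count of 0 allows up to 0.838 CPM in replicate 1 and 0.839 CPM in replicate 2 (3 counts). Intervals are 95% and, unless stated otherwise, exact binomial. The binomial intervals and the floors cover counting error alone, since reads amplified by PCR are not independent molecules. Ratios between different genes are ratios of reads. Whether library preparation captured each sequence equally was not measured, and the SD of the 2 libraries cannot show a bias common to both. Log2 values carry a prior count of 1, and log2 ratios between the libraries are replicate 2 minus replicate 1.

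A gene was called detected with at least 10 counts in both libraries. Ratios between libraries were described for genes with at least 100 counts on average. Scaling was by the library total, with edgeR's TMM factors and DESeq2's size factors as alternatives. The biological coefficient of variation (BCV) was the square root of edgeR's common dispersion with an intercept-only design, TMM factors and genes with at least 10 counts in both libraries. With 2 libraries, no exact test across libraries can reach the 0.05 threshold, since the smallest two-sided sign-flip p is 0.5, so levels are given as mean ± SD (n = 2) without p-values. P-values are given only for tests across genes, which are not independent replicates.

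Before the data were examined, 18 gene lists, 8 pairs of related genes, the polycistronic clusters and the rule for the genes to be named were fixed. The lists were Hox cluster, mesenchyme, cartilage, muscle, epithelium, endothelium, erythroid, leukocyte, neural, sensory, gut with liver and pancreas, pluripotent, Mir17 family clusters, let-7, the Dlk1-Dio3 and Sfmbt2 imprinted regions, the Mir322-Mir503 cluster, and genes with several genomic copies (multi-copy). The genes named are the 20 with the highest mean CPM, up to 4 most abundant members of each list, the 5 largest log2 ratios between the libraries in each direction, and the members of the pairs. Any other gene named was chosen after its values were seen. Members of a list that were not analysed here were left out of its totals. List totals were set against the mesenchyme total within each library, which does not depend on the scaling. List medians were placed among 10000 random lists of the same size. For ratios between libraries the random lists were matched on mean expression in 5 bins. The spread of levels within clusters and the multi-copy difference were tested with 100000 permutations.

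The computations used R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. They were tested on simulated counts for the 1973 genes with 200 genes changed 4-fold. With a simulated BCV of 0.3 the estimate was 0.296. Of the 188 changed genes over the count minimum, 179 (95.2%) passed 2-fold in the right direction after the median ratio was subtracted. The simulated changes were equally many in each direction. The 2-fold counts of the real libraries were made without subtracting the median, so this test does not cover that step. The alternatives covered the strand column, count minimum, scaling, prior count, denominator, multi-copy genes, the most abundant member of each list and each replicate left out in turn.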

Results

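The data are miRNA counts from mouse limb tissue at embryonic day 10.5, a stage at which the limb is a bud of mesenchyme covered by ectoderm. There was 1 group with 2 biological replicates, each a separate pool of embryos (69 in replicate 1 and 51 in replicate 2). Sense counts in miRNA genes totalled 3581672 in replicate 1 and 3576482 in replicate 2, so the depth in miRNA genes was nearly equal although the read totals were not. Of 1973 genes, 348 (17.6%) were detected with at least 10 counts in both libraries. The 250 genes with at least 100 counts on average held 99.9% of the counts. The labels state no contrast, and the comparisons below describe which miRNA genes were abundant in the limb and how far the replicates differed.

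A few genes took most of the counts of uniquely placed reads. Mir335, in an intron of the imprinted gene Mest (chromosome 6, 30741299 to 30741396), was the most abundant at 176336 ± 14589 CPM (SD, n = 2), followed by Mir17 of the growth-associated Mir17-Mir92 cluster (chromosome 14, 115043671 to 115043754, in an exon of Mir17hg) at 90300 ± 4670 CPM. Mir10b (chromosome 2, 74726070 to 74726137, in an intron of Hoxd4) had 69833 ± 19514 CPM and Mir196b (chromosome 6, 52230081 to 52230165, in an annotated exon of Hoxa9) had 63953 ± 14163 CPM. Mir322 on chromosome X (53054255 to 53054349, with no host gene) reached 44410 ± 12882 CPM and Mir10a on chromosome 11 (96317165 to 96317274, no host gene) 38405 ± 5768 CPM. Mir20a, Mir126a, Mir99b and Mir99a completed the first 10, between 20709 and 31072 CPM. The 10 most abundant genes together held 58.2% ± 2.79 of the counts, and the first 20 held 72.4% ± 3.04 (SD, n = 2). Ranks 11 to 20 were Mir130a, Mir26b, Mir214, Mir93, Mir30e, Mir23b, Mir18, Mir130b, Mir106b and Mir92-1, from 20106 down to 9144 CPM. Mir92-1 shares its mature sequence with Mir92-2, so its count was uncertain. The order and shares cover uniquely placed reads in the genes analysed here. Multimapping reads, 32.3% of the mapped reads in replicate 1 and 31.2% in replicate 2, were counted at no gene. Genes of several copies may therefore rank too low, and the order is not that of all mature miRNAs in the limb. Many neighbouring ranks were not separated by the replicates: Mir10b was above Mir196b in replicate 1 (83632 against 53938 CPM) and below it in replicate 2 (56035 against 73968 CPM).

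**Figure D1:**
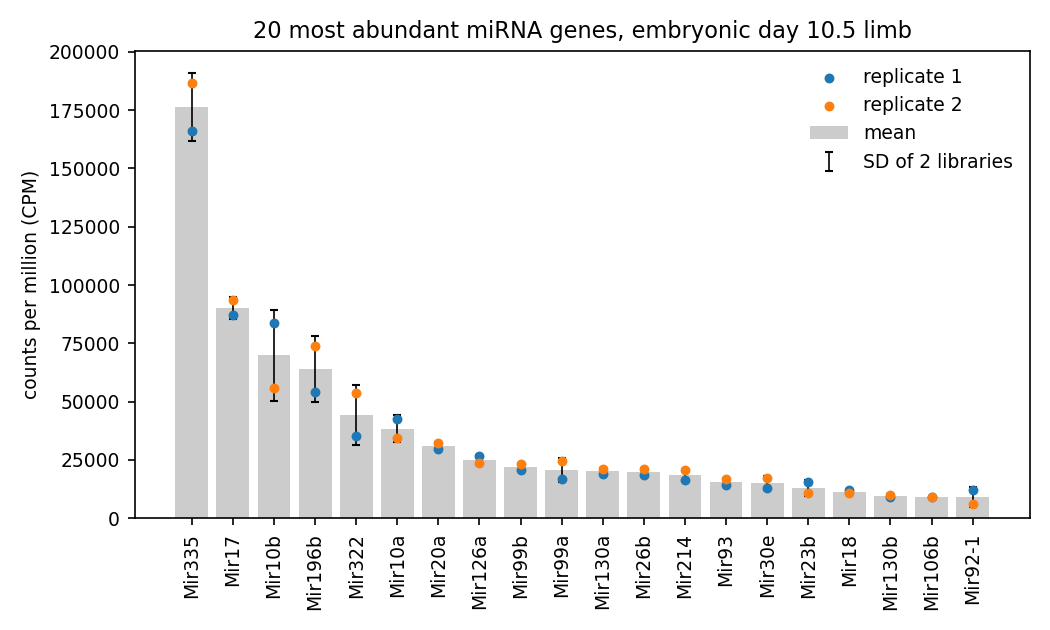
CPM of the 20 most abundant miRNA genes by uniquely placed reads in limb at embryonic day 10.5. Bars are the mean of the 2 libraries, error bars the SD and points the libraries; Mir335 stands highest at a mean of 176336 CPM, and Mir10b and Mir196b change order between the libraries.

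The Hox cluster list, the Mir10 and Mir196 genes that lie among the Hox genes that pattern the body axis and the limb, held 17.4% ± 1.08 of all counts (SD, n = 2), and 5 of 5 members were detected. Mir615, in an intron of Hoxc5 and named after its values were seen, was not on the list and had 4443 ± 1243 CPM. Their total was 6.59-fold the mesenchyme list's, a log2 ratio of 2.72 ± 0.27. Mir10b of the Hoxd cluster was 1.79-fold above Mir10a, which lies between genes of the Hoxb cluster, with a log2 ratio of 0.98 (0.97 to 0.99) in replicate 1 and 0.71 (0.70 to 0.72) in replicate 2. Mir196b was 31.7-fold above Mir196a-1 and Mir196a-2 together, with a log2 ratio of 4.99 ± 0.11. Mir196a-1 and Mir196a-2 encode the same mature sequence and had 39.54 ± 3.004 and 1965 ± 292 CPM. Reads placed at both loci were counted at neither, so the Mir196a counts and this ratio are uncertain.

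Mesenchymal miRNA genes made up 2.65% ± 0.322 of the counts, and 8 of 8 were detected. Mir214 led the list at 18552 ± 2773 CPM (chromosome 1, 162223368 to 162223477, in an exon of the long noncoding RNA gene Dnm3os), followed by Mir143 at 4993 ± 187, Mir199b at 1528 ± 498 and Mir22 at 916 ± 334 CPM. Within this list Mir143 was 67.4-fold above its cluster neighbour Mir145a, with a log2 ratio of 6.07 ± 0.15, and Mir199b was 3.85-fold above Mir199a-1 and Mir199a-2 together, with a log2 ratio of 1.95 ± 0.22. The 3 Mir199 genes share mature sequence, and reads placed at several of their loci were counted at none. This makes their split and the mesenchyme total uncertain, and every ratio to that total carries the same limit.

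Cartilage-associated miRNA genes were detected, and the skeletal and heart muscle genes with uniquely placed reads had low counts. The cartilage list totalled 4394 ± 1864 CPM (3076 in replicate 1 and 5712 in replicate 2), 6.30-fold below mesenchyme, with 3 of 3 members detected. It was led by Mir140 (chromosome 8, 107551244 to 107551313, in Wwp2), a gene active in developing cartilage, with 1978 CPM in replicate 1 and 4767 CPM in replicate 2. Mir140 was above Mir455, an intronic gene of the collagen gene Col27a1, in both libraries, but by unequal amounts: log2 ratios were 1.19 (1.13 to 1.25) and 2.78 (2.72 to 2.84). Mir675, encoded in the H19 transcript, had 242 ± 12.5 CPM. The muscle list totalled 109 ± 34.9 CPM (84.0 and 133), 249-fold below mesenchyme, with a log2 ratio of -7.96 ± 0.30, and 4 of 8 members were detected. Mir206, a skeletal muscle miRNA gene, had the highest mean, with 96 counts in replicate 1 and 350 in replicate 2, but lay below Mir208b (138 counts) in replicate 1 and above it (68 counts) in replicate 2. Mir206 was 18.3-fold above its neighbour Mir133b, which had 4 and 25 counts. Mir208b, Mir208a and Mir499, located in introns of the myosin genes Myh7, Myh6 and Myh7b, had 28.8 ± 13.8, 9.08 ± 3.35 and 4.47 ± 2.37 CPM. Mir1a-1, Mir133a-1 and Mir133a-2, named after their values were seen, had no count in either library, but they share their mature sequences with other loci, and a count of 0 in uniquely placed reads sets no limit on those sequences. The muscle total therefore covers the other members alone.

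Of the other cell types, endothelium and epithelium had high totals and blood and neural lists had low ones in uniquely placed reads. Mir126a, the endothelial miRNA gene within Egfl7 (chromosome 2, 26591357 to 26591429) and the only member of its list, had 25195 ± 2138 CPM. Its log2 ratio to mesenchyme was 0.14 in replicate 1 and -0.28 in replicate 2, so the direction was not settled. The epithelial list totalled 11554 ± 1102 CPM, 2.29-fold below mesenchyme, with 7 of 7 members detected. It was led by Mir205 at 4810 ± 316, Mir429 at 2638 ± 606, Mir203 at 1536 ± 496 and Mir200c at 1399 ± 564 CPM. The sensory list, the Mir183-Mir96-Mir182 cluster of sensory organs, totalled 6481 ± 660 CPM, with Mir182 at 3339 ± 17.9, Mir183 at 2315 ± 556 and Mir96 at 827 ± 85.7 CPM. The gut, liver and pancreas list reached 1147 ± 122 CPM, of which Mir375 made up 1033 ± 99.3 CPM. In that list Mir192 had 53.1 ± 8.64, Mir194-2 had 40.2 ± 0.436 and the liver gene Mir122 had 15.2 ± 13.6 CPM.

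Blood cell lists were low. The erythroid list had 374 ± 149 CPM (480 in replicate 1 and 269 in replicate 2), 73.5-fold below mesenchyme, mostly from Mir451a at 326 ± 136 CPM, with Mir144 at 25.8 ± 3.33 and Mir486 at 22.1 ± 9.86 CPM. The leukocyte list had 692 ± 90.4 CPM, 38.3-fold below mesenchyme, with Mir155 at 490 ± 53.8, Mir223 at 180 ± 30.0, Mir146 at 20.8 ± 5.71 and Mir150 at 1.68 ± 0.789 CPM. Mir142 of this list had no sense value analysed here, and with the antisense counts at its locus added the log2 ratio to mesenchyme was -4.47 in place of -5.26. The neural list had 480 ± 29.7 CPM, 55.1-fold below mesenchyme, and 10 of 18 members were detected. Mir7-1 at 133 ± 12.7, Mir137 at 101 ± 31.1, Mir219a-1 at 61.7 ± 5.47 and Mir128-1 at 55.7 ± 15.95 CPM led it. Most members of the neural list are genes of several copies, whose shared reads were counted at no locus, so its total and the number detected are uncertain. With such genes left out of both lists, the log2 ratio to mesenchyme was -7.68 in place of -5.78. That value rests on the few members left and does not restore the lost reads. For the 3 Mir124a genes, named after their values were seen, no count was found, with the same limit as for the muscle genes of several copies.

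The Mir17 family clusters, which support cell proliferation, held 17.6% ± 0.0491 of the counts, 6.66-fold the mesenchyme total, and 15 of 15 members were detected. Mir19b-1, Mir19b-2, Mir92-1 and Mir92-2 of this list are multi-copy genes whose shared reads were counted at no locus, so the total is uncertain. Mir17 was 24.5-fold above Mir106a, its counterpart in the cluster on chromosome X, with a log2 ratio of 4.62 ± 0.26. Mir20a had 31072 ± 1848, Mir93 had 15558 ± 1593 and Mir18 had 11350 ± 924 CPM. The Mir322-Mir503 cluster on chromosome X held 5.22% ± 1.24, and 7 of 7 members were detected. Mir322 was 31.3-fold above Mir503, with a log2 ratio of 4.97 ± 0.28, and without Mir322 the cluster lay below mesenchyme at a log2 ratio of -1.77 in place of 0.96. Mir351 had 4845 ± 659 and Mir542 had 962 ± 36.6 CPM.

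Imprinted miRNA genes of the Dlk1-Dio3 region on chromosome 12, which are transcribed from the maternal allele, held 5.44% ± 1.33 of the counts, and 41 of 43 members were detected. Of the members analysed here, the most abundant were Mir487b at 7403 ± 1202, Mir411 at 6600 ± 1802, Mir431 at 5914 ± 2325 and Mir369 at 4856 ± 1066 CPM. Mir136, Mir299a, Mir376a, Mir376b, Mir380 and Mir409 of this list had no sense value analysed here, and high antisense counts were found at the loci of Mir409, Mir376a, Mir380 and Mir299a. The Sfmbt2 list stands for the large imprinted cluster on chromosome 2, best known from the placenta. It took every gene named Mir297, Mir466, Mir467 or Mir669 without a check of position, so some members may lie outside that cluster. The list held 0.322% ± 0.0667, with 9 of 69 members detected. Many of its members are numbered copies of repeated hairpins, and reads shared between copies were counted at no locus, so this total and the number detected are uncertain. Mir467c at 1094 ± 144, Mir467d at 936 ± 244, Mir467e at 576 ± 157 and Mir669l at 261 ± 65.7 CPM led it. The let-7 list, whose members increase as embryonic cells differentiate, held 0.775% ± 0.285 (5732 CPM in replicate 1 and 9769 in replicate 2), with 9 of 10 members detected. Mirlet7e and Mirlet7f-1 were not analysed here, and Mirlet7a-1, Mirlet7a-2, Mirlet7c-1, Mirlet7c-2 and Mirlet7f-2 are multi-copy genes whose shared reads were counted at no locus, so the total is uncertain. Mirlet7g had 4250 ± 1427, Mirlet7i 2760 ± 1310, Mirlet7d 334 ± 12 and Mir98 290 ± 88.8 CPM. The pluripotent list, the Mir302 and Mir290 clusters of early embryonic cells, held 0.423% ± 0.280 (6212 CPM in replicate 1 and 2251 in replicate 2), with 10 of 12 members detected. Mir302a had 1597 ± 975, Mir302d 1163 ± 714, Mir302b 1066 ± 830 and Mir302c 201 ± 134 CPM. Most list totals rested on their most abundant member: without it the log2 ratio to mesenchyme went from -2.66 to -4.70 for cartilage, from -4.53 to -7.87 for gut, liver and pancreas, from -6.20 to -9.13 for erythroid, from -5.26 to -7.04 for leukocyte and from -7.96 to -9.19 for muscle. It went from 2.74 to 1.70 for the Mir17 family, from 2.72 to 1.98 for Hox, from -1.20 to -1.97 for epithelium, from -2.03 to -3.09 for sensory, from -1.82 to -2.98 for let-7 and from -3.05 to -3.66 for Sfmbt2. List medians lay at percentile 95.8 or above among random lists drawn from the 1973 genes, most of which were not detected, except for the Sfmbt2 list at percentile 0, where the loss of shared reads may lower the counts.

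**Figure D2:**
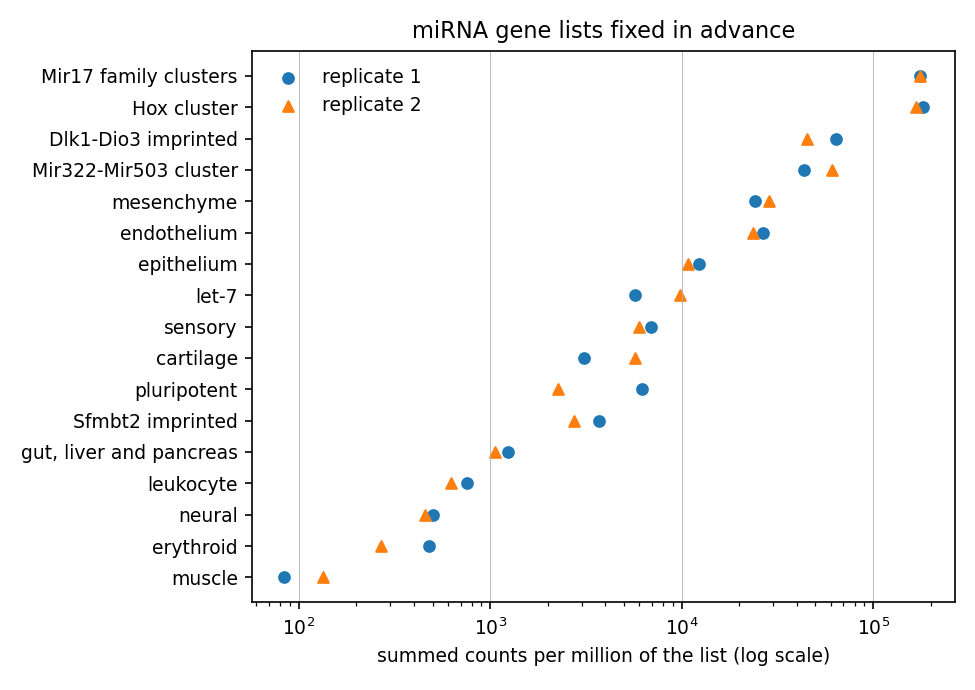
Summed CPM of 17 gene lists in replicate 1 (circles) and replicate 2 (triangles), on a log scale. The Mir17 family and Hox cluster lists lie highest at means of 175863 and 174196 CPM and the muscle list lowest at 109 CPM; the pluripotent, cartilage, erythroid and let-7 lists show wide gaps between the libraries.

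Members of the same primary transcript had closer levels than random genes. Across 38 clusters with 122 genes, the median SD of log2 CPM within a cluster was 2.18, against 3.35 when the same genes were assigned to clusters at random (one-sided permutation test across genes, p = 0.00304). With genes detected in both libraries alone, the value was 2.07 and the same permutation test no longer passed (p = 0.0566). The 59 genes with several genomic copies had a mean log2 CPM of 4.22, against 5.52 for the 212 other genes of the lists and clusters. These included the 69 genes of the Sfmbt2 list, of which 44 had no count and many are themselves numbered copies. The comparison set was therefore not one of single-copy genes. This difference of -1.30 did not pass the two-sided permutation test (p = 0.0928), and it passed with a prior count of 5 (p = 0.0310) and against all other detected genes (p = 1e-05, the smallest these permutations can give), a set that holds no undetected gene. Without the Sfmbt2 genes, a choice made after seeing the data, the other 143 had a mean of 8.39 and the difference was -4.17 (two-sided permutation test, p = 1e-05). Mir181b-2 at 2060 ± 885, Mir196a-2 at 1965 ± 292 and Mir16-1 at 1842 ± 305 CPM followed Mir92-1 among the multi-copy genes.

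The replicates ranked the genes alike and differed in level by more than counting error. Across the 250 genes with at least 100 counts on average, Pearson's r of log2 CPM was 0.974 and Spearman's rho 0.9747, which are correlations across genes, not across independent samples. The SD of the log2 ratio was 0.66 (bootstrap interval over genes 0.55 to 0.76), against 0.094 from counting alone. The chi-square of the counts was 140638 on 249 degrees of freedom, which shows no more than that the tables are not copies of each other. They were counted as 2 samples because the labels name separate pools. The BCV by edgeR was 0.301 (0.281 to 0.326). That chi-square interval takes the 348 genes as independent, which they are not, so it is too narrow. Values of 0.334 without TMM and 0.246 at 100 counts or more in both libraries lay outside it. The median log2 ratio was -0.27, and TMM scaling shifted all ratios by 0.28 to a median of 0.01. The ratios of lists are therefore also given relative to the median of all genes. Over 2-fold differences were found for 27 genes (10.8%), of which 3 were higher and 24 lower in replicate 2. TMM scaling gave 6 higher and 14 lower, as did DESeq2 size factors. Simulated libraries with no change gave 28 of 251 genes (11.2%) over 2-fold at a BCV of 0.3, a value close to the one estimated from these libraries, so the simulation is no independent reference for how far replicates differ.

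**Figure D3:**
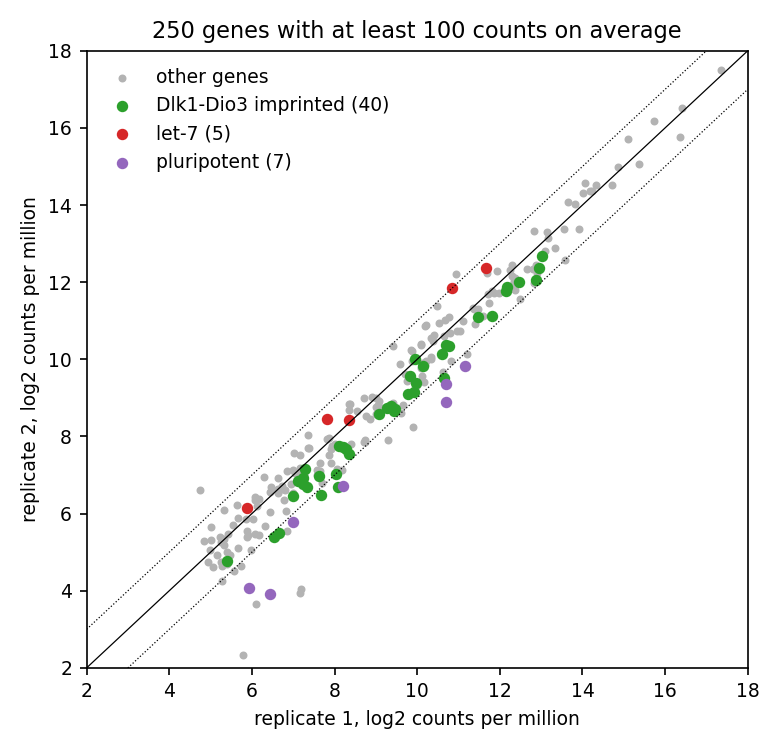
Log2 CPM in replicate 1 (x axis) and replicate 2 (y axis) for 250 miRNA genes, with the line of equality (solid) and 2-fold lines (dotted). Coloured points are the Dlk1-Dio3 imprinted (40), let-7 (5) and pluripotent (7) genes; all 7 pluripotent genes lie below the lower dotted line, and 6 of 7 do so under TMM scaling.

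The difference between the libraries was shared by the members of some lists. All 5 measured let-7 genes were higher in replicate 2, with a median log2 ratio of 0.64. This median was at percentile 100 of the expression-matched random lists (their 95% range was -0.82 to 0.27) and lay 0.91 above the median of all genes. Here and below, percentiles and ranges belong to the list median before the median of all genes is subtracted. With genes of at least 10 counts on average the let-7 median was 0.32. Mirlet7i had a log2 ratio of 1.01 (0.96 to 1.05), Mirlet7g of 0.70 (0.67 to 0.73) and Mir98 of 0.635 (0.508 to 0.765). The intervals of Mirlet7d at 0.07 (-0.04 to 0.19) and the multi-copy gene Mirlet7f-2 at 0.26 (-0.01 to 0.53) included 0. Both ratios lay above the median of all genes. All 7 measured genes of the pluripotent list were lower in replicate 2 and by more than 2-fold. Their median was -1.48, at percentile 0 (range -0.62 to 0.29), which is -1.21 relative to all genes. Under TMM scaling 6 of the 7 stayed over 2-fold. Mir294 had 309 counts in replicate 1 and 54 in replicate 2, and Mir302b 5918 and 1712. In the Dlk1-Dio3 region 37 of 40 measured genes lay below the median of all genes. The list median was -0.56, at percentile 0 (range -0.31 to 0.01), which is -0.28 relative to all genes. Of the mesenchyme list, 6 of 7 measured genes lay above the median of all genes, 0.58 above it at the median and at percentile 99.05, with Mir22 as the exception at a log2 ratio of -0.76. Multi-copy genes lay above it in 22 of 28 cases, at percentile 100. Members of a cluster come from a shared transcript, so these counts are not counts of independent genes. The random lists drew genes singly, so for such lists the ranges may be too narrow and the percentiles too extreme.

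Other lists moved less uniformly. Relative to the median of all genes, 3 of 5 Hox cluster genes, 2 of 3 cartilage, 4 of 6 Mir322-Mir503, 4 of 5 neural, 2 of 3 sensory, 2 of 3 gut, liver and pancreas, 7 of 14 Mir17 family, 3 of 7 epithelial and 2 of 6 Sfmbt2 genes were above it, and each list's median lay between percentile 15.9 and 90.6 of its matched lists. The muscle and leukocyte lists had 2 measured genes each and the endothelial and erythroid lists 1 each, too few for a percentile. The erythroid gene Mir451a had a log2 ratio of -0.88 (-1.0015 to -0.75).

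**Figure D4:**
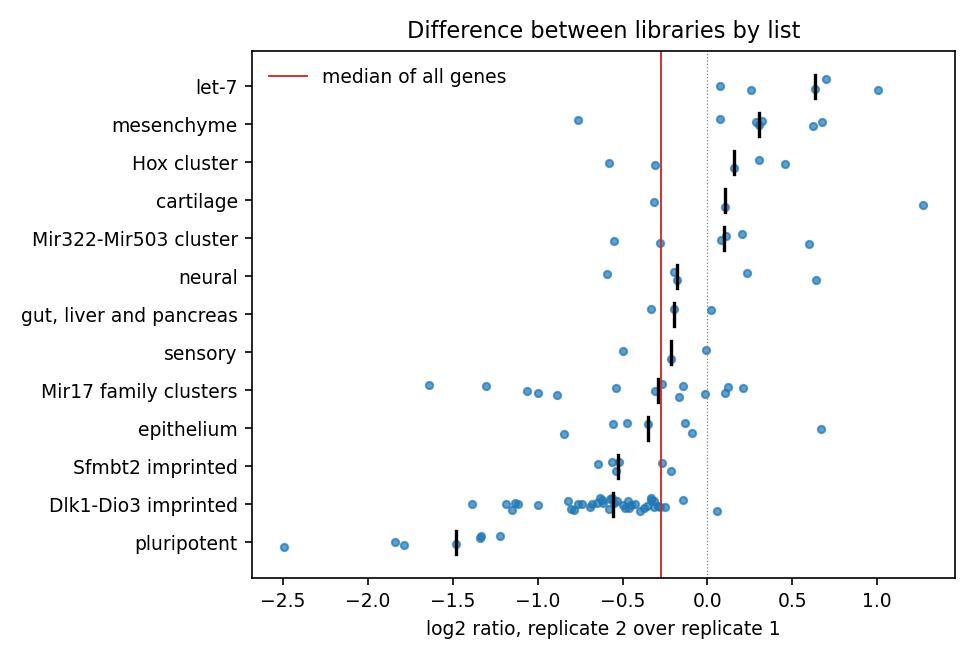
Log2 ratio of replicate 2 over replicate 1 for members of 13 gene lists with at least 100 counts on average; each point is a gene, black bars are list medians, the red line is the median of all genes at -0.27 and the dotted line marks 0. The let-7 list has the highest median at 0.64 and the pluripotent list the lowest at -1.48.

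The largest ratios for single genes were as follows. Mir206 had the highest ratio of replicate 2 over replicate 1, with a log2 ratio of 1.86 (1.54 to 2.21), followed by Mir140 at 1.27 (1.23 to 1.31), Mirlet7i, Mir125b-1 at 0.91 (0.84 to 0.98) and Mir181b-2 at 0.90 (0.86 to 0.95). The last 2 are genes with several copies. The lowest ratio was that of Mir5126 (chromosome 1, 84695839 to 84695915) at -3.39 (-4.24 to -2.76). Mir1247 in the noncoding RNA gene Dio3os (chromosome 12, 110278048 to 110278129) followed at -3.20 (-3.65 to -2.82), and then Gm26117 in an exon of Adgrb1 (chromosome 15, 74563821 to 74563915) at -3.13 (-3.56 to -2.76). Mir294 at -2.49 (-2.96 to -2.09) and Mir6538 in an intron of Rnf144a (chromosome 12, 26414901 to 26415010) at -2.42 (-2.94 to -1.98) were the next. The 5 lowest genes had between 18 and 59 counts in replicate 2. The hairpins of Mir5126, Mir1247, Gm26117 and Mir6538 had a GC content of 83.1%, 74.4%, 91.6% and 75.5%, and the 7 measured genes with at least 70% were all lower in replicate 2. With 1 pool per replicate, these ratios compare the libraries and carry no test of a condition.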

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

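All tests in this part were chosen after the result was seen. The antisense column, which is outside the main measurement, held 84234 counts in replicate 1 and 61736 in replicate 2. It stood far above the limit of a count of 0 at 10 miRNA genes with at least 100 antisense counts in both libraries, which held 99.8% of all antisense counts. Mean antisense counts were 29926 at Gm24321, opposite Mir409, and 10447 at Gm25301, opposite Mir378a. They were 8117.5 at Gm25927, opposite Mirlet7e, 6582 at Gm24083, opposite Mir191, and 5473.5 at Gm25252, opposite Mir376a. Gm25750, opposite Mir380, had 4542.5, Mir299b, opposite Mir299a, had 3743, and Mir142b, opposite Mir142, had 1861.5. Mir497b, opposite Mir497, had 1793, and Mir3074-1, opposite Mir24-1, had 322.5. At the first of these loci (chromosome 12, 109743158 to 109743237) the sense count was 0 in both libraries and the antisense counts were 40032 and 19820. The 10 genes were chosen by their antisense counts and not by the rule for named genes.

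Libraries that do not keep strand are argued against as the source of these antisense counts: at 49 genes with at least 10000 sense counts in both libraries and no opposite miRNA gene, antisense counts reached at most 0.0252% of the sense counts. Reads of a miRNA gene on the opposite strand are a candidate explanation, since 10 of the 10 loci overlap an annotated miRNA gene on the other strand, against 32 of all 1973 genes (1.62%; Fisher's exact test, two-sided, p = 2.68e-19). For each of the 32 such pairs 1 member was analysed here. If so, the antisense counts may stand for Mir409, Mirlet7e, Mir142 and others that the totals above leave out, and Mir409 would rank 23 by abundance at 8359 ± 3985 CPM (SD, n = 2). No biological explanation was tested.

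Genes with several genomic copies were lower than their neighbours in the same transcript. In 10 of 10 clusters with both kinds and a single-copy mean of at least 100 CPM, the multi-copy members were lower, with a median log2 difference of -3.51 (mean -4.14 ± 2.85 SD, exact sign-flip permutation test, p = 0.00195, the smallest possible). Choosing clusters by their single-copy level favours a difference of this sign, and without that minimum 15 of 15 clusters had the same direction, with a median of -3.42. Lower transcription of these loci is argued against, since a shared transcript leaves both kinds equal in transcription. Reads shared between copies and then left out as multimapping may account for it, and multimapping reads were 32.3% and 31.2% of the mapped reads. Unequal processing or stability of the members was not tested and stays open, and no biological explanation was tested.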

How the results depend on the processing

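Of 166 alternatives computed for 35 results, 135 left the value within its spread (counts within 1.5 times) and tests on their side of the threshold, 26 moved a value, 1 weakened and 3 strengthened a test and 1 reversed a direction. The values with each replicate left out were all among the 135, although endothelium against mesenchyme, which was not called, had opposite signs (-0.28 without replicate 1 and 0.14 without replicate 2). For a list ratio or a pair, the value of 1 library always lies within the SD of the 2 libraries. That outcome was therefore fixed in advance and shows no stability. The alternatives with opposite-strand counts, without the Sfmbt2 genes in the multi-copy comparison and those for the let-7 and pluripotent medians were chosen after seeing the data. No paired analysis was possible because there is only 1 group. The top-10 share was 33.1% with all mapped reads as denominator, by construction. The SD of the log2 ratio was 0.98 with no filter. The BCV was 0.334 without TMM and 0.246 at 100 counts or more in both libraries. Genes over 2-fold numbered 54 at 10 or more counts on average, 8 higher and 46 lower in replicate 2, since genes with few counts enter. TMM and DESeq2 scaling each gave 6 higher and 14 lower. Without its most abundant member, the log2 ratio of a list to mesenchyme was 1.98 for Hox, 1.70 for Mir17 family, -1.97 for epithelium, -2.98 for let-7, -3.09 for sensory, -3.66 for Sfmbt2, -4.70 for cartilage, -6.25 for neural, -7.04 for leukocyte, -7.87 for gut, liver and pancreas, -9.13 for erythroid and -9.19 for muscle. The Mir322-Mir503 cluster reversed to -1.77, as its top member holds most of its counts. The endothelial list has 1 member and gave no such value. The neural list was at -7.68 without multi-copy genes, since most of its members are multi-copy. With opposite-strand counts added as genes, the leukocyte list was at -4.47 and let-7 at -1.43, since Mir142 and Mirlet7e enter. The permutation test within clusters weakened to 2.07 (p = 0.0566) for detected genes, with fewer genes tested. The multi-copy difference passed its permutation test with a prior count of 5 (-1.44, p = 0.0310) and against all other detected genes (-3.33, p = 1e-05). Without the Sfmbt2 genes, many of them numbered copies with no counts, it was -4.17 (permutation test, p = 1e-05). The let-7 median ratio went from 0.64 to 0.32 at 10 or more counts on average, labelled as within its spread. Where no reason is given, the cause was not tested. Depth limits statements below 0.838 CPM.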

Other observations

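Of the tests in this part, the GC correction was fixed before its result was seen and the others were chosen after. The let-7 list was higher and the pluripotent list lower in replicate 2, with medians 2.12 apart on the log2 scale. An exact permutation test of the 5 and 7 members gave p = 0.00126, the smallest of 792 splits, but both lists were picked for their direction and their members share transcripts, so the p describes these genes alone. TMM scaling adds the same 0.28 to every log2 ratio, so it could reverse neither list and gives no further support.

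A bias between the libraries that follows hairpin GC content is argued against as the whole cause. After a quadratic trend on hairpin GC was removed, the gap was 2.15. The GC content of the sequenced arms was not used, so a bias acting on that was not tested. Relative to mesenchyme, the totals of 6 of 6 lists of other cell types were lower in replicate 2, but these ratios share a denominator that was itself higher there, and relative to all genes 5 of the 6 list medians lay between -0.08 and 0.09 (erythroid, with 1 measured gene, at -0.61), so this count decides nothing. A lower share of limb cells in replicate 1 stays open for the pluripotent list, whose total relative to mesenchyme changed by -1.71. The 21 markers of other cell types had a median log2 ratio of -0.21 (SD 0.40), 1.27 above that of the pluripotent list. But 7 of them are epithelial genes, which may come from the limb ectoderm, so the set does not measure a share of limb cells. The neural, sensory and gut, liver and pancreas lists had medians of -0.18, -0.21 and -0.20. As sets, their measured genes therefore did not share the fall. Genes under 100 counts on average are not in these medians. Some of those fell as far, such as Mir122 (89 counts in replicate 1 and 20 in replicate 2) and Mir219a-2 (141 and 24). Others changed little, such as Mir7-2 (52 and 47) and Mir218-1 (18 and 22). For the let-7 list a lower share of limb cells also stays open, as its median lay 0.33 above that of the mesenchyme list, within the spread of the members (SD 0.48). A later mean stage of the embryos pooled in replicate 2 is a hypothesis that may account for the pattern, with its gap of 2.12. The labels give embryonic day 10.5 for both pools and no finer stage, and the pattern it would explain is the one that led to it, so it stays open. Differences in dissection or library preparation between the pools also stay open, untested.

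Across the 250 genes, which are not independent, hairpin GC content and the log2 ratio had a Pearson's r of -0.19 and a Spearman's rho of 0.014. The 7 genes with a hairpin GC of at least 70%, a limit set after seeing the data, were all lower in replicate 2, by -1.89 on average relative to the other genes, and without them Pearson's r was 0.080. Of these, 4 are among the 5 lowest ratios, whose GC content led to that limit, so this difference describes the picked genes alone. The share of unmapped reads was 32.3% in replicate 1 and 18.6% in replicate 2.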
